A study of Mus musculus with 4 samples.

How the data were processed

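Gene expression was measured by RNA sequencing in regulatory T cells (Treg, CD4-positive T cells that express the transcription factor Foxp3) sorted from mouse spleen. The labels give 2 groups, resting Treg and activated Treg, with 2 samples in each, and state that the samples came from independent animals. Total RNA was isolated with a column kit and turned into libraries with a template-switching kit for very low inputs (SMART-seq v4). Such libraries are amplified by PCR and carry no molecular identifiers, so counts are reads, not molecules, and counting error is only part of the error.

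The submitters' processing notes list STAR 2.4.0c, featureCounts, DESeq2 and the mm10 mouse genome build, without roles or order. The annotation release, the strand setting and any read filter are not given in the sources used here. The deposited count table holds raw counts for 38924 Ensembl gene identifiers, from featureCounts per its name, with whole numbers and no summary entries. A second table by the authors holds regularized log2 values from DESeq2, a log2 scale in which low counts are shrunk towards the gene's mean. It lists the same 38924 identifiers with values from -2.33 to 19.8, and whether its transformation used the groups is not given in the sources used here.

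The headings of the count table name the group of each column but repeat one replicate number over both columns of a group. The columns were therefore assigned to groups only, and the 4 libraries are called resting A, resting B, activated A and activated B; the letters are names and pair nothing. The regularized log table carries the replicate numbers 1 and 2, which were used as printed. Gene symbols and positions came from GENCODE M21, which is on the mm10 (GRCm38) build; 37607 of the 38924 identifiers matched. Ribosomal proteins, globins and the pairs Ly6c1 and Ly6c2, Csf2rb and Csf2rb2, and Lyz1 and Lyz2 have close relatives or pseudogenes in the genome, and how reads shared between them were counted is not given in the sources used here.

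Library totals were 20699024 counts in resting A, 31851982 in resting B, 29332058 in activated A and 20282062 in activated B. In the smallest library 1 CPM, a count scaled to a common library total, corresponds to 20.3 counts. CPM values were scaled with trimmed mean of M values (TMM) factors, which lay between 0.963 and 1.04. The mean and the standard deviation (SD) of each group are over 2 libraries. Fold changes are activated over resting, from edgeR with a prior count of 2. Their standard error (SE) was derived as the log2 fold change over the square root of edgeR's F statistic. It is approximate, above all for genes with few counts in a group.

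The tests were fixed before the data were examined. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 14235, and were tested with edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3) on group alone, with Benjamini-Hochberg adjustment and a threshold of 0.05. The replicate numbers were not used to pair samples, because the labels describe independent animals. The biological coefficient of variation was 0.352, with 2 residual and 3.10 prior degrees of freedom. With 2 libraries against 2, an exact two-sided permutation test cannot go below p = 0.333, so no such test was run on single genes.

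A set of 25 gene lists was also fixed before the data were examined, from textbook knowledge of T cells, metabolism, stress responses and other spleen cell types. Each was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 25 lists. Camera compares a list with all other genes. It was repeated with a correlation estimated from the data, where its test has only the 2 residual degrees of freedom of the fit. A call lost there need not reflect correlated genes. Fry was run beside camera, with its directional and its mixed test. Counts of members past the threshold are also given adjusted over the list alone. Lists of 4 sort markers and of 5 sex-linked genes were read as values only.

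The rule for naming genes had 3 parts. It took up to 12 genes per direction with the largest fold change among genes past the threshold, with a mean of at least 4 log2 CPM and with both activated libraries on one side of both resting ones, leaving out predicted genes and antigen-receptor segments. It took from each list 2 to 4 members with the smallest adjusted p and well-expressed members that did not pass. It also took Foxo1, Foxo3, Klf2, Ccr7, S1pr1, Il7r and the sort markers; some genes it named are not reported here. The first part named 0 genes from the edgeR calls; the same rule was then applied to the DESeq2 calls, a choice made after the data were seen.

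The procedure was tested on simulated data with the means and library sizes of these libraries, starting from their estimated spread. With one spread for all genes of similar level, edgeR called 13 of 58 genes changed by 2-fold, 59 of 71 changed by 4-fold and 70 of 71 changed by 8-fold, with 8 calls among unchanged genes and 26 by DESeq2. With a spread that also varied between genes, as estimated here, edgeR and limma-voom called 0 of 58, 0 of 70 and 0 of 71. DESeq2 then called 8, 53 and 64 of these, together with 161 genes that had not been changed. Camera called 0 of 25 lists of independent unchanged genes.

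The alternatives were other normalizations (DESeq2's size factors, upper quartile), no filter or a stricter one (mean count of at least 50), DESeq2 1.42.0, limma-voom, limma on the authors' regularized log values, a test against a fold change of 2, leaving out each library in turn, an estimated correlation, and a replicate block. The count table gave no pairing for the planned block in edgeR, so a block in limma on the regularized log values and both possible pairings in edgeR were added after the data were seen, as were list tests without dendritic cell genes. When a library was left out, the lone sample of its group was assumed to vary like the other group. Genes were also filtered again in each such fit, which tested 15146 to 16050 genes in place of 14235. Counts of genes and list medians from these fits can therefore cover other genes, and their shifts are not due to the lost library alone.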

Results

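Resting and activated Treg from mouse spleen, 2 samples of each from independent animals, were compared by low-input RNA sequencing. Treg are the T cells that restrain immune responses. The title of the series concerns graded activity of the transcription factor Foxo1 in Treg, and its design text asks how the transcriptomes of these 2 populations differ. The labels print the same surface marker gate for both populations. The count table held 20699024 and 31851982 counts for resting A and B and 29332058 and 20282062 for activated A and B, with 19061, 18928, 19610 and 23398 genes detected. Across genes, which are not independent replicates, log2 CPM correlated with r = 0.955 between the resting libraries and r = 0.954 between the activated ones. Correlations between libraries of different groups ranged from 0.923 to 0.954.

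The genes that define the sort were read first, as a check of the labels. Cd44, an adhesion receptor of activated T cells, rose from 179 ± 47.9 CPM (SD, n = 2) in resting Treg to 332 ± 4.25 in activated Treg. Adjusted over the list alone, the edgeR adjusted p was 0.0246 for Cd44, with both activated libraries above both resting ones. Cd4 was at 931 ± 49.4 and 1169 ± 106 CPM and did not pass. Foxp3 was at 36.9 ± 2.64 and 37.1 ± 0.606 CPM, a log2 fold change of 0.01 ± 0.18 (SE), and its sign turned without resting B (-0.077) and without activated A (-0.00037). Foxp3 lies on chromosome X from 7573644 to 7595245 (mm10, GENCODE M21).

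By camera with its preset correlation, genes of lymphoid homing and quiescence were lower as a list in activated Treg, and effector, tissue homing and helper lineage genes were higher as lists. None of the 4 lists passed, with adjusted p = 0.183, 0.377, 0.241 and 0.183 with an estimated correlation. Adjusted over the list alone, 18 of 24, 3 of 34, 5 of 30 and 8 of 23 members passed in the direction of their list. S1pr1, the receptor that lets T cells leave lymphoid organs, fell from 878 ± 3.96 to 337 ± 7.51 CPM, and Ccr7, the chemokine receptor for entry into lymph nodes, fell from 700.5 ± 109 to 243 ± 61.1 CPM. Id2, an inhibitor of E protein transcription factors, rose from 96.4 ± 9.73 to 300.2 ± 79.6 CPM. Cxcr6, a chemokine receptor of tissue T cells, rose from 14.97 ± 6.68 to 127 ± 21.3 CPM. These 4 genes passed when adjusted over the list alone (edgeR adjusted p = 0.00332, 0.00609, 0.0373 and 0.0111 in this order). Unless another tool is named, a single gene that passed or did not pass was judged by edgeR adjusted over the list alone. In each gene said here to have risen or fallen, both activated libraries lay on one side of both resting ones. In the same libraries, dendritic cell markers were also higher in activated Treg, with a list median log2 fold change of 2.27.

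**Figure D1:**
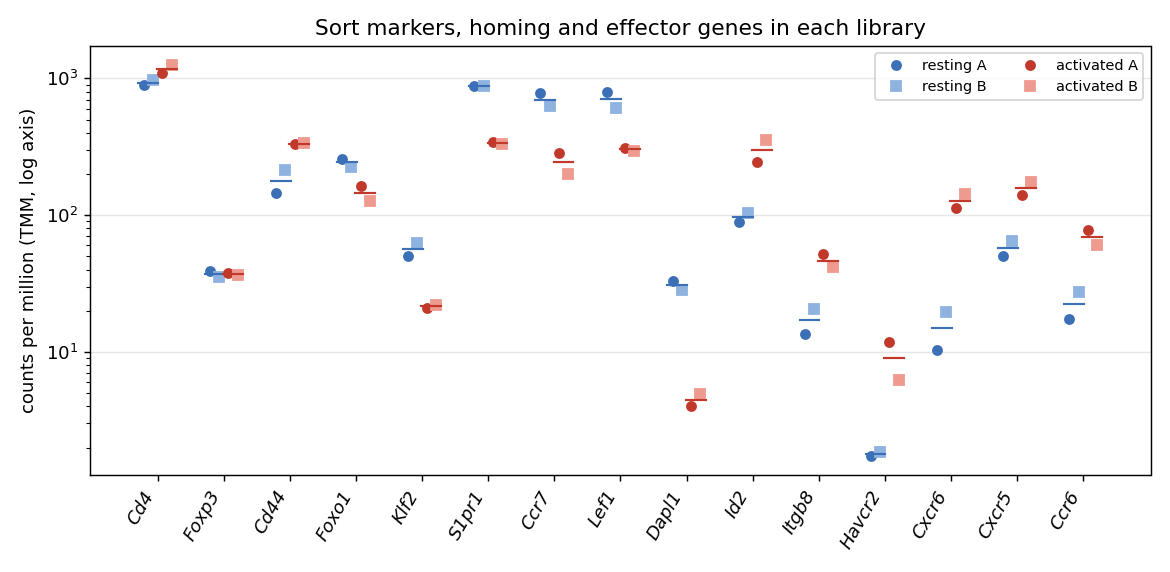
CPM (TMM-scaled, log axis) of sort marker, homing and effector genes in the 2 resting (blue) and 2 activated (red) libraries; each point is a library and each short line a group mean. S1pr1 lies at 875 and 881 CPM in the resting libraries and at 343 and 332 in the activated ones, while Foxp3 lies between 35.0 and 38.7 in all 4.

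Over all 14235 genes tested, edgeR called 0 genes higher and 0 lower, with a smallest adjusted p of 0.266, so no member of any list passed over all genes. At an unadjusted p under 0.05 edgeR counted 897 genes higher and 371 lower, 1268 in all. DESeq2 called 324 higher and 118 lower, limma-voom called 0 with 1273 at an unadjusted p under 0.05, and limma on the authors' regularized log values called 0 with 1371. In all 442 genes called by DESeq2 both activated libraries lay on one side of both resting ones and the unadjusted edgeR p was under 0.05. Such separation held for 5293 tested genes, 37.2%, where chance gives 33.3%. The edgeR counts changed with single libraries: 334 higher and 36 lower without resting A, 176 and 22 without resting B, 59 and 3 without activated B, and 0 of both without activated A. On simulated data with a spread that varied between genes, DESeq2 called 161 unchanged genes and edgeR recovered 0 of 71 genes changed by 8-fold. That spread was on average above the one estimated here, so these numbers do not measure the error of the real calls. With one spread for genes of similar level, DESeq2 called 26 unchanged genes and edgeR 8, and edgeR recovered 70 of 71. Camera with its preset correlation called 17 of 25 gene lists, 12 higher and 5 lower, and called 0 with an estimated correlation. That repeat had 2 residual degrees of freedom. It also lost lists whose estimate lay below the preset 0.01, such as helper lineage (-0.023) and cholesterol genes (0.0046).

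The list of lymphoid homing and quiescence genes had 24 measured members, of which 18 fell and 0 rose when adjusted over the list alone; both activated libraries lay below both resting ones in each of the 18. DESeq2 over all genes called 15 lower and 0 higher. The list's median log2 fold change was -1.19, lower than other genes by camera (adjusted p = 3.41e-38). The list did not pass with adjusted p = 0.183 with an estimated correlation. Dapl1 fell by 2.76 ± 0.26 on the log2 scale, from 30.7 ± 3.23 to 4.47 ± 0.643 CPM. Igfbp4 fell by 2.49 ± 0.31 and Ly6c1 by 2.64 ± 0.40, though Ly6c1 shares sequence with Ly6c2. Klf2, a transcription factor that drives the S1pr1 gene, fell from 56.7 ± 8.85 to 21.6 ± 0.781 CPM, and Lef1, a transcription factor of naive T cells, from 702 ± 137 to 303 ± 12.8. Slfn2, at 1075 ± 33.8 and 953 ± 233 CPM, and Il7r, at 235 ± 87.7 and 274 ± 93.4 CPM, did not pass. Their values changed sign without activated A, to 0.065 for Slfn2 and -0.17 for Il7r, and Il7r also without resting B (-0.13).

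Foxo1 itself was at 243 ± 23.1 CPM in resting and 145 ± 25.04 in activated Treg, a log2 fold change of -0.75 ± 0.20. Both activated libraries lay below both resting ones, but the difference did not pass (adjusted p = 0.133 over the list alone by edgeR, adjusted p = 0.0615 by DESeq2). Foxo1 lies on chromosome 3 from 52268336 to 52353221, on the plus strand. Foxo3 was at 54.9 ± 5.84 and 40.2 ± 1.98 CPM and did not pass either. Of the genes that Foxo1 is known to drive in T cells, Klf2, S1pr1 and Ccr7 fell and Il7r did not pass. Of the 29 measured genes of the Foxo family and the Foxo-PI3K-Akt axis, only Trib2, a pseudokinase, changed when adjusted over the list alone: it fell from 424 ± 1.44 to 201 ± 0.709 CPM. Gabarapl1, an autophagy gene, had a log2 fold change of 1.26 ± 0.28 and Inpp5d, a phosphatase that opposes PI3K, one of 0.08 ± 0.17. Neither passed by edgeR over the list alone, and DESeq2 called Gabarapl1 (adjusted p = 0.0141). The list's median was -0.18, lower than other genes by camera (adjusted p = 0.00297). This call was lost with adjusted p = 0.397 with an estimated correlation, and the median was -0.09 without resting A, -0.30 without activated A and -0.09 without activated B.

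Effector Treg genes rose as a list, with 32 of 34 measured members above 0, a median log2 fold change of 1.31 and a camera adjusted p of 1.10e-17. It did not pass with adjusted p = 0.377 with an estimated correlation. Adjusted over the list alone, 3 members rose and 0 fell by edgeR; 15 were higher and 0 lower at an unadjusted p under 0.05, and DESeq2 over all genes called 9 higher and 0 lower. The 3 were Id2 (log2 fold change 1.64 ± 0.25), Havcr2, an inhibitory receptor (2.28 ± 0.45), and Itgb8, an integrin subunit that activates TGF-β (1.44 ± 0.29). Id2, at 244 and 357 CPM in activated A and B, was higher in B, as the list was (median log2 ratio of A to B -0.88). Havcr2 (11.9 and 6.21 CPM) and Itgb8 (51.6 and 41.5 CPM) were higher in activated A. That direction is shared with the plasmacytoid dendritic cell genes described below (median log2 ratio 1.68). Tnfrsf4, a costimulatory receptor, was at 423 ± 192 and 747 ± 419 CPM and did not pass; its log2 fold change was 0.09 without activated B and 1.36 without resting B. The list's median was 0.84 without resting A, 2.22 without resting B and 0.78 without activated B. Of the 22 measured Treg core genes 0 passed by edgeR over the list alone, with 4 higher and 2 lower at an unadjusted p under 0.05, while DESeq2 over all genes called 1 higher and 2 lower. The list did not pass by camera (median 0.28, camera adjusted p = 0.133), except without resting B (0.65, adjusted p = 0.000787); without resting A the median was 0.13 (adjusted p = 0.672). Gpr83, at 420 ± 31.3 and 219 ± 30.3 CPM, was called lower by DESeq2 (adjusted p = 0.00194), and Nt5e, the ectoenzyme CD73, at 301 ± 29.0 and 522 ± 47.2 CPM, higher (DESeq2 adjusted p = 0.0106). The interleukin 2 receptor genes Il2ra (-0.37 ± 0.19) and Il2rb (0.17 ± 0.25) did not pass by edgeR or DESeq2; Il2rb turned to -0.077 without resting A and to -0.034 without activated B.

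Tissue homing receptors rose as a list (median log2 fold change 0.68, camera adjusted p = 3.82e-09). The list did not pass with adjusted p = 0.241 with an estimated correlation, and its median was 1.64 without resting B. Of 30 measured members 5 rose and 1 fell when adjusted over the list alone, and DESeq2 over all genes called 6 higher and 1 lower. Cxcr5, the receptor for entry into B cell follicles, rose from 57.4 ± 10.2 to 158 ± 23.6 CPM, and Ccr6 from 22.4 ± 7.08 to 69.0 ± 11.9. Itga6, an integrin subunit that binds laminin, fell from 149 ± 16.3 to 80.3 ± 8.27 CPM. Itgb2, highly expressed at 947 ± 8.73 and 1038 ± 24.5 CPM, did not pass. Helper lineage factors and cytokines rose as well, with 8 of 23 measured members higher and 1 lower adjusted over the list alone, a median of 1.08 and a camera adjusted p of 1.85e-09. DESeq2 over all genes called 5 higher and 0 lower. The list did not pass with adjusted p = 0.183 with an estimated correlation. Ifng rose from 1.89 ± 0.274 to 6.97 ± 0.864 CPM, Il4 from 0.650 ± 0.233 to 5.21 ± 2.74 and Csf1 from 15.9 ± 8.40 to 62.6 ± 25.4, while Il4ra fell from 405 ± 32.1 to 260.2 ± 0.623. Il23r rose from 1 count in each resting library to 81 counts in activated A and 22 in activated B. Ifngr1 was at 331 ± 27.9 and 373 ± 16.6 CPM and did not pass.

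**Figure D2:**
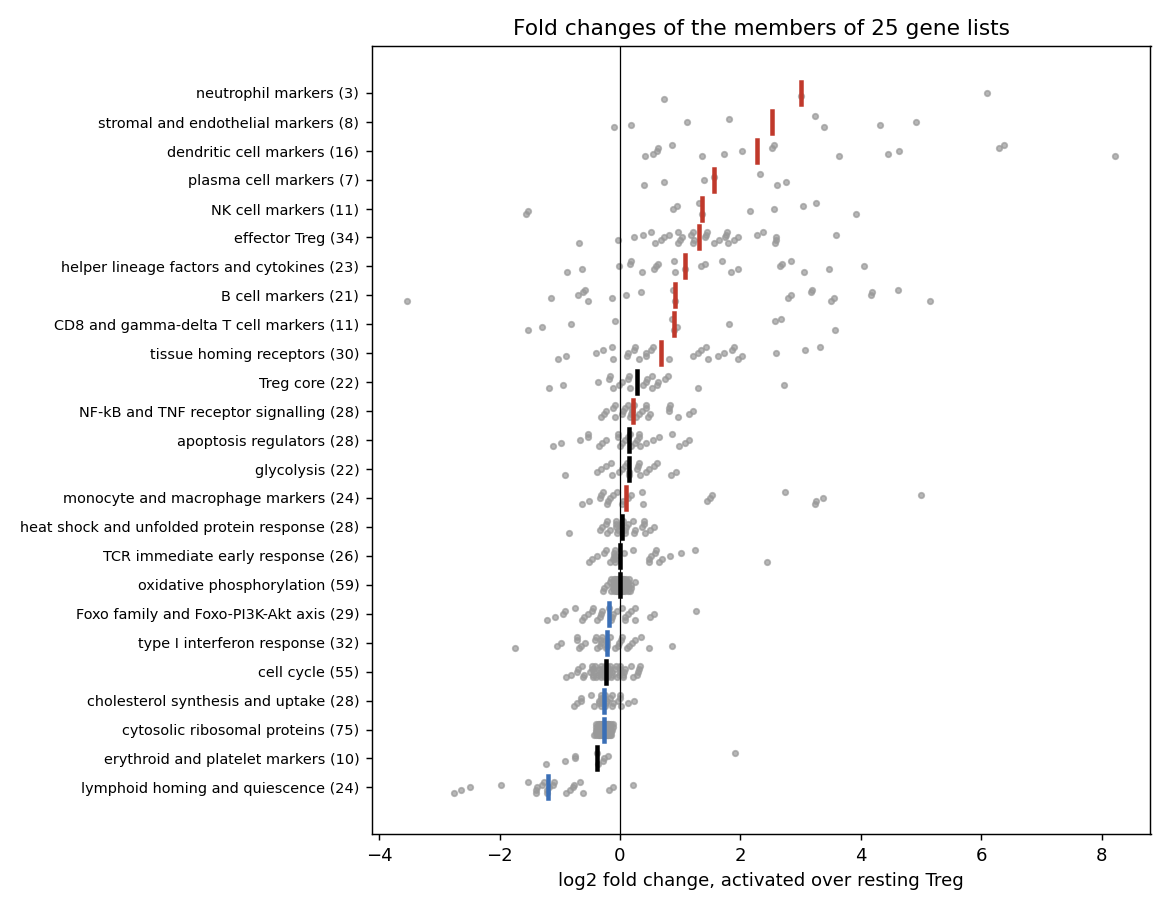
Log2 fold change (activated over resting, horizontal axis) of the measured members of 25 gene lists, one grey point per gene and the number measured in brackets; thick lines are list medians, red or blue where camera with its preset correlation called the list higher or lower and black otherwise. The medians run from -1.19 for lymphoid homing and quiescence to 2.998 for neutrophil markers, of which 3 of 16 were measured.

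Cytosolic ribosomal protein genes were lower by a small, even step: all 75 measured members lay below 0, with a median of -0.27 and a camera adjusted p of 4.75e-10. The list did not pass with adjusted p = 0.522 with an estimated correlation, its median was -0.13 without activated A, and edgeR over the list alone called 0 members, with 2 lower at an unadjusted p under 0.05 and 0 called by DESeq2. Rpl5 was at 361 ± 12.2 and 267 ± 4.36 CPM, Rps3a1 at 2106 ± 111 and 1592 ± 8.40 CPM and Rpl4 at 4379 ± 653 and 3337 ± 611 CPM, though reads shared with pseudogenes limit these values. Cholesterol synthesis and uptake genes were lower as a list, with 24 of 28 measured members below 0 (median -0.26, camera adjusted p = 0.000239). This list did not pass with adjusted p = 0.183 with an estimated correlation. Over the list alone edgeR called 0 members, with 4 lower at an unadjusted p under 0.05, and DESeq2 called 0: Hmgcs1 was at 143 ± 9.93 and 86.9 ± 16.0 CPM and Sqle at 79.9 ± 6.26 and 50.9 ± 8.03. Type I interferon response genes were lower too, with 23 of 32 measured members below 0 (median -0.22, camera adjusted p = 0.000376). Their call was lost with adjusted p = 0.397 with an estimated correlation. Oas2 was at 10.5 ± 1.14 and 3.06 ± 0.209 CPM and Ifit3 at 59.4 ± 12.1 and 30.0 ± 4.89, neither past the threshold by edgeR over the list alone, where 0 members passed and 5 were lower at an unadjusted p under 0.05. DESeq2 called both lower (adjusted p = 0.00142 for Oas2 and 0.0309 for Ifit3).

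NF-kB and TNF receptor genes rose slightly as a list (median 0.22, camera adjusted p = 0.0108), with 22 of 28 measured members above 0. The call was lost with adjusted p = 0.436 with an estimated correlation, without resting A (adjusted p = 0.249) and without activated B (adjusted p = 0.487), and the median was 0.40 without activated A. Icam1 (0.82 ± 0.18), Relb (0.83 ± 0.25) and Nfkbia (0.19 ± 0.21, and -0.040 without activated B) did not pass by edgeR over the list alone, where 0 members passed and 4 were higher and 0 lower at an unadjusted p under 0.05. DESeq2 called Icam1 (adjusted p = 0.0215). Lists of the T cell receptor immediate early response, apoptosis regulators, glycolysis, oxidative phosphorylation, and heat shock and unfolded protein response did not pass by camera, and edgeR over the list alone called 0 of their members. At an unadjusted p under 0.05 edgeR counted, in this order, 4 higher and 1 lower, 3 and 4, 2 and 0, 0 and 0, and 0 and 0; DESeq2 called 1 higher and 1 lower among apoptosis regulators and 0 in the other 4 lists. In the same order, their medians were 0.0014, 0.16, 0.15, 0.00036 and 0.036, with camera adjusted p of 0.393, 0.922, 0.392, 0.397 and 0.864. The mean was 0.28 for the early response, far from its median, and -0.0021 for oxidative phosphorylation, opposite in sign to its median. Camera's direction for oxidative phosphorylation was down. The early response median was 0.044 without resting A, 0.40 without resting B, 0.403 without activated A and 0.057 without activated B. The apoptosis median was 0.076 without resting A, 0.28 without resting B, 0.276 without activated A and 0.074 without activated B. The glycolysis median was 0.0034 without resting A, 0.33 without resting B and 0.29 without activated A and turned to -0.058 without activated B, and the heat shock median to -0.021 without activated A and -0.0202 without activated B. Among the early response genes Egr2 was at 64.6 ± 14.1 and 130.03 ± 46.3 CPM, Nfkbid at 30.2 ± 5.002 and 54.1 ± 10.4, Myc at 269 ± 28.9 and 189 ± 6.93, and Cd5 at 699 ± 12.1 and 655 ± 55.9, with its sign turned without activated A (0.00052). DESeq2 called Casp1, at 33.1 ± 5.97 and 70.0 ± 6.94 CPM (adjusted p = 0.004), and the death gene Bcl2l11, at 69.8 ± 13.7 and 35.2 ± 3.81 (adjusted p = 0.0174), but not Mcl1, at 208 ± 8.14 and 144 ± 16.4. Hif1a had a log2 fold change of 0.61 ± 0.20, Aldoc of 0.93 ± 0.36 and Pkm of 0.30 ± 0.34, which was -0.16 without activated B. Among genes of the respiratory chain Ndufs1 (-0.27 ± 0.21), Ndufa6 (-0.22 ± 0.18) and Atp5a1 (-0.06 ± 0.16, and 0.0055 without resting B) did not pass. Oxidative phosphorylation genes passed as a list, in both directions, without resting A (median -0.15, adjusted p = 0.000455), activated A (0.22, adjusted p = 0.0463) or activated B (-0.27, adjusted p = 2.19e-06). Hspa5 (0.41 ± 0.17), Xbp1 (0.40 ± 0.16) and Hspa8 (-0.16 ± 0.15), chaperone and stress genes, did not pass.

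Cell cycle genes did not separate the groups: 0 of 55 measured members passed by edgeR over the list alone or by DESeq2, 1 was lower at an unadjusted p under 0.05, 44 lay below 0, and the list did not pass (median -0.22, camera adjusted p = 0.282). Libraries of one group differed more than the group means for the proliferation genes Mki67 and Top2a. Mki67 was at 26.0 and 131 CPM in resting A and B and at 50.1 and 74.8 CPM in activated A and B, and Top2a at 79.4, 337, 120 and 230 CPM. Ndc80 (-0.90 ± 0.34), E2f2 (-0.60 ± 0.42) and Hmgb2 (-0.28 ± 0.64) did not pass. E2f2 turned to 0.0047 without resting B, and Hmgb2 to 0.87 without resting B and 0.13 without activated A. The list passed in opposite directions without single libraries: its median was -0.94 without resting A (adjusted p = 5.30e-34), 1.10 without resting B (adjusted p = 1.37e-14) and -0.83 without activated B (adjusted p = 4.44e-06). It was 0.15, not past the threshold, without activated A.

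Markers of other spleen cell types were measured in the same libraries, and 8 of 9 such lists were higher in activated Treg by camera with its preset correlation. None of the 8 passed with an estimated correlation, where the smallest adjusted p was 0.183. Dendritic cell markers rose, with all 16 measured members above 0, 10 of them past the threshold and 0 lower adjusted over the list alone (median 2.27, camera adjusted p = 4.46e-18). This list did not pass with adjusted p = 0.238 with an estimated correlation, and its median was 1.40 without activated A. Siglech, a lectin of plasmacytoid dendritic cells, had 16 and 8 counts in the resting libraries and 8548 and 1190 in activated A and B, a log2 fold change of 8.22 ± 1.08. Irf8, a transcription factor of dendritic cells and B cells, rose from 32.4 ± 3.39 to 190.0 ± 114 CPM and Flt3, a growth factor receptor of dendritic cells, from 0.876 ± 0.271 to 20.7 ± 18.4. Cst3 rose from 98.3 ± 19.7 to 151 ± 0.282 CPM. Of 21 measured B cell markers 11 rose and 1 fell adjusted over the list alone (median 0.92, camera adjusted p = 5.06e-08). Their call was lost with adjusted p = 0.183 with an estimated correlation. Cd22 rose from 3.27 ± 0.913 to 24.0 ± 4.34 CPM and Cd74, the invariant chain of MHC class II, from 332 ± 212 to 2307 ± 1553. Without the dendritic cell genes, 14 of them picked after their values were seen, the B cell list no longer passed (median -0.32, adjusted p = 0.939), and neither did the macrophage list (-0.053, adjusted p = 0.417). In both, camera's direction stayed up, opposite in sign to the median.

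**Figure D3:**
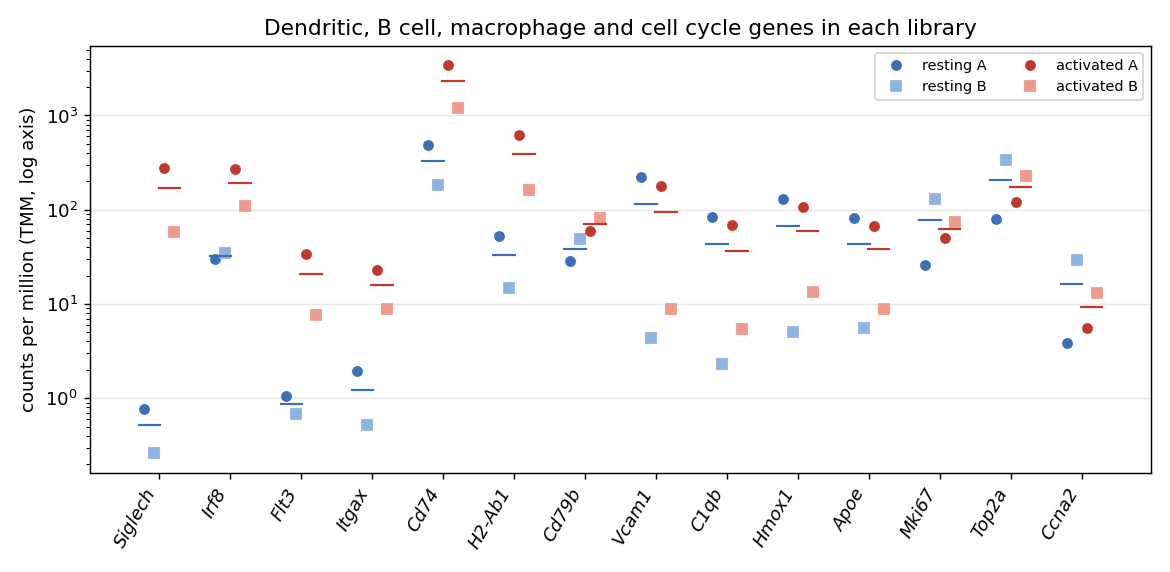
CPM (TMM-scaled, log axis) of dendritic cell, B cell, macrophage and cell cycle genes in the 2 resting (blue) and 2 activated (red) libraries; each point is a library and each short line a group mean. Siglech, Flt3 and Itgax lie higher in both activated libraries and higher in activated A than in activated B, whereas Vcam1, C1qb, Hmox1 and Apoe lie higher in resting A than in resting B and higher in activated A than in activated B.

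Monocyte and macrophage markers followed single libraries. Vcam1, abundant in splenic red pulp macrophages, had 4605 and 135 counts in resting A and B and 5464 and 181 in activated A and B, and its log2 fold change of -0.28 ± 1.86 turned to 4.37 without resting A and 0.65 without activated B. Camera called the list higher (adjusted p = 0.00892) on a median of 0.10 and a mean of 0.85, while edgeR over the list alone called 0 of 24 measured members, with 2 higher at an unadjusted p under 0.05, and DESeq2 called 1 higher. It was lost with adjusted p = 0.809 with an estimated correlation. The median was 4.20 without resting A, -0.73 without resting B (adjusted p = 0.0595), -2.29 without activated A (adjusted p = 0.375) and 0.90 without activated B. The lysozyme genes Lyz1 and Lyz2, which share sequence, had 2 and 0 against 218 and 10 counts and 242 and 66 against 3207 and 518 counts and did not pass by edgeR; DESeq2 called Lyz1 (adjusted p = 0.00684).

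Markers of plasma cells, NK cells, CD8 and gamma-delta T cells, neutrophils and stromal cells were also higher as lists. The medians were 1.56 over 7 plasma cell genes (adjusted p = 1.06e-05), 1.37 over 11 NK cell genes (adjusted p = 1.63e-05) and 0.89 over 11 CD8 and gamma-delta T cell genes (adjusted p = 0.00668). They were 2.998 over 3 neutrophil genes (adjusted p = 7.35e-07) and 2.53 over 8 stromal and endothelial genes (adjusted p = 1.52e-08). The count table held 12 plasma cell, 17 NK cell, 12 CD8 and gamma-delta, 16 neutrophil and 20 stromal and endothelial genes of these lists. Members too low to pass the filter were not tested, so the medians do not describe the whole lists. Against the preset correlation of 0.01, the estimates were -0.062 for plasma cell, 0.026 for NK cell and -0.11 for stromal genes. They were 0.27 for neutrophil genes and 0.14 for CD8 and gamma-delta genes. With 2 residual degrees of freedom, a lost call does not show that correlated genes explain it. None of these 5 calls held, with adjusted p = 0.183 with an estimated correlation for 4 of them and adjusted p = 0.397 for the CD8 and gamma-delta list. That list was also lost without activated A (median 0.58, adjusted p = 0.0665) and was at 0.59 without resting A. The NK cell median was 2.06 without resting A, 2.31 without resting B, 1.76 without activated A and 1.88 without activated B. All lay above the 1.37 of the full fit. The stromal median was 1.66 without activated B. Genes were filtered again in these fits, so such medians can cover other members and do not show the effect of a library alone. The stromal list was the only one of 25 past the threshold by fry's directional test (adjusted p = 0.0283). Fry's mixed test, which ignores direction, called it too, along with the lymphoid homing, helper lineage, interferon, plasma cell, neutrophil, NK cell, CD8 and gamma-delta, and erythroid lists, with adjusted p from 0.0268 to 0.0352. Ccl5, a chemokine of cytotoxic and memory T cells, rose from 14.5 ± 8.41 to 175 ± 42.5 CPM and Zbtb16, a transcription factor of innate-like T cells, from 0.227 ± 0.0907 to 1.85 ± 0.665. Cd8a had a log2 fold change of 1.81 ± 0.69, did not pass, and was at 0.58 without activated A. Klrb1c, the NK receptor NK1.1, rose from 3.01 ± 1.23 to 13.7 ± 2.85 CPM, and Klrb1b from 0 counts in both resting libraries to 42 and 17. Prf1, the pore protein perforin, was at 22.4 ± 12.8 and 7.55 ± 4.06 CPM and did not pass.

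The plasma cell gene Mzb1 rose from 0.797 ± 0.441 to 5.90 ± 0.255 CPM, while Sdc1 (0.374 ± 0.117 and 2.20 ± 1.23 CPM) and Igkc (28.9 ± 23.0 and 85.9 ± 35.7 CPM) did not pass. Mmp9, a gelatinase of neutrophils, rose from 0 and 4 counts to 339 and 188, and Ltf from 2 and 0 to 38 and 11. The endothelial genes Kdr and Cdh5 rose from 1 and 2 to 176 and 47 counts and from 1 and 10 to 220 and 73 counts. Erythroid and platelet markers did not pass as a list (median -0.37, camera adjusted p = 0.397), except without resting B (-1.20, adjusted p = 0.000295). The median turned to 2.11 without resting A and 0.16 without activated B. Adjusted over that list alone 1 member rose and 2 fell. Car2, a carbonic anhydrase, rose from 8.23 ± 1.40 to 31.0 ± 3.87 CPM, and Gata1, an erythroid transcription factor, fell from 48.8 ± 7.199 to 20.9 ± 5.99. The globin Hbb-bs had 288 and 4 counts in the resting and 214 and 6 in the activated libraries, and its log2 fold change of -0.92 ± 1.95 was 4.18 without resting A. Among sex-linked genes Xist had 3336, 4145, 8027 and 2959 counts in the 4 libraries and 4 Y-linked genes had 0; the log2 fold change of Xist, 0.46 ± 0.32, was -0.017 without activated A.

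The naming rule, applied after the data were seen to the DESeq2 calls, gave 12 genes in each direction. The 12 that rose were Siglech, Lifr, Cd209a, Csf2rb2, Rnase6, Kmo, Pltp, Csf2rb, Alox5ap, Ly6d, Ly6c2 and Plac8. In all 12 activated A was above activated B. Siglech (chromosome 7, from 55768178 to 55778925) had a DESeq2 adjusted p of 3.55e-09. Cd209a, a lectin of dendritic cells, rose by 6.38 ± 0.97 on the log2 scale (DESeq2 adjusted p = 5.25e-15), and Ly6d by 4.62 ± 0.64 (1.27e-14). Plac8 rose least of the 12, by 3.80 ± 0.63. Reads shared between Csf2rb and Csf2rb2, and between Ly6c1 and Ly6c2, limit these values. Those that fell included Dapl1, Ly6c1, Cnn3, Igfbp4, Myo6, Tdrp, Satb1, Sema4a, Treml2, Gpr146 and Trpm1. Myo6, an unconventional myosin on chromosome 9 from 80165031 to 80311729, fell from 59.6 ± 0.903 to 12.5 ± 0.722 CPM (DESeq2 adjusted p = 9.14e-16). Satb1, a chromatin organizer of T cells, fell from 249.9 ± 102 to 63.2 ± 24.2 CPM (DESeq2 adjusted p = 0.000124), and Dapl1 (chromosome 2, from 59484653 to 59505020) had a DESeq2 adjusted p of 4.17e-14.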

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

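The blocked fits, both edgeR pairings and the list tests without dendritic cell genes were chosen only after the data were seen. The 0 genes higher and 0 lower by edgeR held with DESeq2's size factors, upper-quartile scaling, a mean count of at least 50, limma-voom, limma on the authors' regularized log values and a test against a fold change of 2. They became 675 and 177 without a filter, where the median of all genes moved to 0.12, and 324 and 118 with DESeq2. Leaving out 1 library gave 0 to 334 higher and 0 to 36 lower. Replicate numbers do not establish pairing. A replicate block gave 1027 and 525 in limma on the regularized log values. In edgeR, where the headings name no pairing, it gave 755 and 371 with A paired to A and B to B, and 26 and 0 with A paired to B. Macrophage markers had a median log2 ratio of A to B of 4.73 in resting and 2.96 in activated Treg. From replicate 1 to 2 they differed by 3.35 and 2.13. For cell cycle genes these values were -2.07 and -0.93, and -1.84 and -0.84. Such values argue against A paired to B as the pairing of equal numbers, though columns were not assigned by values. All 442 DESeq2 calls and all 1126 with A paired to A were among the 1552 of the limma block. The lists past the threshold, 17, became 16 to 19 in the other settings, 14 of 24 without dendritic cell genes and 0 with an estimated correlation. Over 110 named genes, 1216 alternative values kept direction and side of the threshold, 400 kept direction and passed, and 27 changed sign; over lists, leaving aside the estimated correlation, with which all 17 calls were lost, and the lists without dendritic cell genes, 306 were the same, 9 passed, 7 no longer passed and 28 changed sign. The cause was not tested for these changes.

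Outside leave-one-out, Foxp3 turned to -0.026 without a filter and -0.00083 on regularized log values with and without a block. Vcam1 was 0.71 with limma-voom, 0.30 on regularized log values with and without a block, and 0.20 and 0.33 in the edgeR blocks; Hbb-bs was 0.90 with limma-voom. The oxidative phosphorylation median was -0.041 without a filter, -0.022 with limma-voom, -0.020 on regularized log values with and without a block, and -0.0118 and -0.0123 in the edgeR blocks. The early response median was -0.044 with the stricter filter, -0.058 with limma-voom, -0.024 on regularized log values with and without a block, and -0.0147 and -0.0176 in the edgeR blocks. The cell cycle median was 0.013 on regularized log values with and without a block, and 0.0028 and 0.023 in the edgeR blocks; the erythroid median was 0.60 with limma-voom. Leave-one-out log2 fold changes ranged from -0.077 to 0.072 for the Foxp3 log2 fold change, -0.45 to 0.065 for Slfn2, -0.17 to 0.65 for Il7r, -0.077 to 0.44 for Il2rb, -1.04 to 0.0047 for E2f2, -0.92 to 0.87 for Hmgb2, -0.19 to 0.00052 for Cd5, -0.040 to 0.39 for Nfkbia, -0.16 to 0.66 for Pkm, -0.15 to 0.0055 for Atp5a1, -3.65 to 4.37 for the Vcam1 log2 fold change, -4.22 to 4.18 for the Hbb-bs log2 fold change and -0.017 to 0.82 for Xist. List medians ranged from -0.94 to 1.10 for cell cycle, -0.058 to 0.33 for glycolysis, -0.27 to 0.22 for oxidative phosphorylation, -0.021 to 0.062 for heat shock, -2.29 to 4.20 for macrophages and -1.54 to 2.11 for erythroid genes. Depth limits genes such as Il23r and Kdr, with 1 or 2 counts in each resting library, whose folds are not given; Ltf and Lyz1 were not tested without activated A.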

Other observations

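In this part, the tests of B cells, of Treg expression, of dendritic cells as a source of effector genes, of fewer T cells and of shared animals were chosen only after the result was seen. A further list of 18 genes of plasmacytoid dendritic cells (pDC), chosen without looking at its values and with 0 genes in a list fixed before, had 15 measured members. Of these 14 lay above 0 in activated Treg, 12 of them by over 1 on the log2 scale. Smim5 had 15 and 22 counts in the resting and 1013 and 156 in the activated libraries, Paqr5 had 2 and 7 against 438 and 145, and Havcr1 and Epha2 had 0 in both resting libraries. Tlr7 was the exception (-0.62 ± 0.65).

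A further list of 17 genes of red pulp macrophages, also with 0 genes in a list fixed before, followed the replicate numbers of the regularized log table. All 17 were higher in replicate 1 of resting Treg and 14 in replicate 1 of activated Treg. Slc40a1, the iron exporter ferroportin, had 6875 and 130 counts in resting A and B and 9185 and 68 in activated A and B. Cd5l, a protein secreted by macrophages, had 492 and 24 against 530 and 12. Activated B also stood apart in genes far from T cell function: 213 of 1434 odorant and vomeronasal receptor genes were detected there, against 119, 47 and 63 in resting A, resting B and activated A.

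The first pattern is the rise of pDC genes in activated Treg, with activated A above activated B. For 9 B cell genes not shared with dendritic cells, B cells as its source are argued against. Their median log2 fold change was -0.58 with an error of 0.23, and 2 lay above 0. The evidence is limited, as all 9 were in lists already examined when this subset was picked. Of the 9, 5 exceeded 1 CPM in both resting libraries, and Cd22, a B cell marker that rose, is not among them. Here and below, an error is the median absolute deviation over a list's genes divided by the square root of their number. It measures spread between genes, not between samples. A candidate explanation is pDC among the cells sorted as activated, which a gate on Foxp3 should remove. The second pDC list had a median of 2.65, the same with members at 0 set to a bound of 3 counts. Its median log2 ratio of A to B was 1.68 in activated and 0.08 in resting Treg. Macrophage markers had a ratio of 2.96 between activated A and B, so this ratio alone cannot tell pDC from the macrophage signal. Some members were far higher in resting A than in resting B, as macrophage markers were. Clec12a, whose fold change is the list's median, had 184 and 10 counts there, and Pld4 had 345 and 59. Abundant pDC transcripts were there, Siglech at 279 and 58.7 CPM and Pld4 with 6911 and 1158 counts, but 6 of the 15 measured genes exceeded 1 CPM in both resting libraries, so part of the list was not particular to the activated ones. Expression by activated Treg themselves stays open, as the first pDC list, picked after its values were seen, differed by 1.75 between the activated libraries and no value here forbids that.

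The second pattern is the macrophage signal in replicate 1 of both groups. A trend with transcript length or GC content, which explained 3.30% of the variance between resting replicates and 12.6% between activated ones, is argued against: after its removal the macrophage list still differed by 3.42 in resting and 2.18 in activated Treg. The second red pulp list differed by 3.51 in resting and 2.24 in activated Treg, which is consistent with red pulp macrophages, or RNA from them, in the replicate 1 samples although a gate on CD4 and Foxp3 should remove such cells. No biological explanation was tested, since the labels give none for a difference between replicates.

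The third pattern is that effector Treg and cell cycle genes were higher in replicate 2 of both groups, by 0.99 and 1.84 in resting and 0.82 and 0.84 in activated Treg. Fewer T cells in replicate 1 would lower pan T cell genes as well. The 16 pan T cell genes were higher in replicate 2 by 0.24 (error 0.04) and 0.38 (error 0.08), less than the effector list by more than both errors. This argues against fewer T cells as the whole cause in these samples. The errors are over genes of a single pair of samples per group and hold no sampling error. A first bound, a fixed fraction of the effector difference, was not met and was replaced after the result was seen. Removing the trend with length and GC content left at least 0.980 of each difference, which argues against that trend. Animals, age, day or gate shared by samples with the same number stay open: the deviations of same-numbered samples correlated across genes (r = 0.652), but the labels give none of these per sample.

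The effector Treg list had a median log2 ratio of activated A to B of -0.88 with an error of 0.10, opposite in sign to the pDC lists. Between resting A and B its ratio was -1.16, so the sign was present in resting Treg too. The ratio therefore cannot tell whether the same pDC add to the rise of the effector Treg list. Over the 3 splits of the 4 libraries into pairs the real one gave 17 lists past camera's threshold and the highest other gave 8, so 1 split was as large; 3 splits cannot give a share under 0.05. The split of A against B libraries had 2059 genes at an unadjusted edgeR p under 0.05 against 1268 for the real one. The crossed split, resting A and activated B against the others, had 34. More genes thus differed between A and B than between the groups. The main test had no block, so this difference lies within its error.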
